A study of Macaca mulatta with 9 samples.

How the data were processed

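RNA was measured in whole blood of 9 rhesus macaques (Macaca mulatta), 3 in each of 3 groups. Per the series design, the animals were assigned to the groups at random and injected with PBS (the vehicle), with extracellular vesicles (EV) named FBMSC, or with EV from antler blastema progenitor cells (ABPC). The sample descriptions call the PBS animals Old, numbered 1 to 3; the labels give no dose, duration or age. Each library comes from a different animal, so the 3 libraries of a group are biological replicates.

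Per the labels' protocols, libraries were made from total RNA with a NEBNext Ultra RNA kit and sequenced as paired-end reads on an Illumina platform, and the genome build was Mmul_10. The labels do not mention removal of globin RNA. The aligner, the counting program and the handling of reads that fit several genes are not given in the sources used here. The deposited table holds 24371 genes and 9 columns, all mapped to samples, with 0 columns left over. Its values are log2 values as deposited: 0.5 was added to a per-million value before the log2, a reading checked on the values themselves, whose lowest is -1. The per-million values sum to 1000000 in every library but ABPC_EV replicate 2 (1000002), and they behave like TPM, in which each gene's count is divided by a gene length and then by the library's total. Because the total is fixed, a lower share of one abundant transcript raises the listed values of all others.

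The table gives no counts. Whole read numbers were recovered by searching, per gene, for one divisor that turns its values in all libraries into whole numbers. With a tolerance of 0.001, 21550 of the 21551 genes above 0 in 2 or more samples (99.995%) came out whole. Of 1000 genes whose values had been perturbed, 0 did, but those were above 0 in every library and had a much shorter search. The shares are therefore not alike, and a gene above 0 in few libraries may come out whole by chance. The recovered reads served for the depth per library and for alternatives; they are reconstructed, and a divisor shared by every library of a gene cannot be told from a multiple of it. The table pairs no gene IDs with names, so its own names were used: 14048 of 24371 are in the pairing of gene IDs with symbols, 20451 are in the RefSeq gene table, which is of another assembly, and 9085 are LOC numbers. No coordinates are given, because the builds differ.

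Design, tests, gene lists and most alternatives were fixed before the data were examined. The planned count test needed counts, so the design's stated test for a normalized unit was used: limma 3.58.1 with a trend in R 4.3.3, on log2(value + 1), for genes with a value of at least 1 in 3 or more samples (10596 genes), with all 9 samples in 1 fit and group as the only term. p-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. limma's camera tested the gene lists (preset inter-gene correlation 0.01, adjusted over 29 lists with at least 5 tested members); it compares a list's genes with all other genes, so a list's change is given relative to the median log2 fold change of all genes. The same test with a correlation estimated from the data stands beside each call, and fry was run as another alternative. Counts of list members past the threshold are given over all genes tested and adjusted over the list alone.

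Of 30 lists fixed beforehand, the blood cell lists were erythroid and globin, neutrophil, immature granule neutrophil, eosinophil and basophil, monocyte, T cell, cytotoxic and NK, B cell, plasma cell, platelet and megakaryocyte, and dendritic cell. The process lists were ribosomal protein, mitochondrial genome, oxidative phosphorylation, antioxidant, heat shock and unfolded protein, proteasome, autophagy and lysosome, interferon-stimulated, inflammation, MHC class II and antigen presentation, regulatory and exhausted T cell, immediate early stress, senescence, DNA repair and telomere, cell cycle, cholesterol and lipid, glycolysis and hypoxia, and TGF-beta, matrix and bone. A sex-linked check list had 1 of its 9 genes in the table and 0 tested, so that check is void.

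Named genes follow a rule fixed beforehand: per comparison, the 10 genes with the smallest p in each direction that carry a symbol, pass the threshold and have no overlap between the groups' libraries (all that pass where fewer do), and for each list the member with the smallest p in the direction of the list's change, with up to 3 more where the list passes. The direction of a list's change was the one camera gives, and its members were taken from that side of the median of all genes; in 18 of 87 tests of a list it differs in sign from the list's relative median. The further 3 members were named only for lists that also pass with an estimated correlation, a limit set after the data were seen. Also chosen after their values were seen were HBB, HBA, HBA1, ALAS2, CA1, BNIP3L and RORA, and members of lists in which 5 or fewer members passed; each is marked where it is named.

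Alternatives fixed beforehand were: the erythroid list taken out before scaling, no filter, a filter at 10, pseudocounts of 0.1 and 5, quantile normalization, limma-voom with quality weights (planned for counts and run on the recovered reads), only the 6 samples compared, the replicate number as a block, a threshold of 0.1, an unadjusted p with a 2-fold change, and each library left out in turn. The other alternatives planned for counts only, count models and their normalizations, were tried once on the recovered reads, late, and their values are not used, because those reads are rebuilt from a TPM-like unit and are not counts. Their counts of genes after scaling differed from those given here: DESeq2 called genes in each of the 3 comparisons, and edgeR with TMM did not in any. The limma-voom fit on the same reads is kept as an exception. Added after the data were seen were median-ratio scaling (each library divided by the median ratio of its genes to their geometric means over the 9 libraries, from 13350 genes above 0 in all), limma-voom on recovered reads with the same kind of scaling, both again with each library left out, quantile normalization for the lists, a pseudocount of 0.5, disjoint controls for the agreement between comparisons, and the estimated correlation with each library left out. Median-ratio scaling sets the typical gene to no change, so it answers which genes moved against the others and cannot show whether total RNA changed.

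Single values of 3 libraries against 3 were compared by an exact two-sided permutation test (scipy 1.17.1 in Python 3.11.15), whose smallest possible p is 0.1. On simulated data with the 10596 genes of ABPC_EV against PBS and equal library factors, the limma test recovered 40% of genes changed by a log2 fold of 1 and 93% of those changed by 2, with 3 unchanged genes called. With the real library factors it called 9863 unchanged genes before median-ratio scaling and 5 after it, when 40% and 93% were recovered. The simulation put in the same factors that the scaling takes out, with balanced rises and falls and noise independent between genes. It cannot show whether calls on the real values are false, or whether the scaling suits those values. The changed genes were drawn only from those above the median level, so these rates do not cover low values. In a simulation of the list test with the preset correlation and equal library factors, the moved list passed and 0 unmoved lists did. Its genes were drawn independently, so it does not show how the test behaves for lists whose genes vary together. Recovered reads ranged from 11.7 M in ABPC_EV replicate 2 to 14.5 M in PBS replicate 2 (1 M is 1000000); they set how well a low value is known, and differences between animals add to that error. numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures.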

Results

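The series measured gene expression in whole blood of rhesus macaques after injection of PBS, FBMSC_EV or ABPC_EV, with 3 animals per group; its title names age-related phenotypes as the topic. Total depth was similar in the groups: recovered reads averaged 12.8 ± 1.43 M under PBS, 13.1 ± 0.387 M under FBMSC_EV and 12.3 ± 0.691 M under ABPC_EV (SD, n = 3 each; 1 M is 1000000). The ratio of ABPC_EV to PBS was 0.958 (exact permutation p = 0.6). Outside the erythroid list depth was not similar: these reads averaged 4.31 ± 1.14 M, 6.28 ± 0.969 M and 7.56 ± 0.666 M in that order (SD, n = 3 each), 1.75 times as many under ABPC_EV as under PBS (exact permutation p = 0.1, the smallest possible). Values are per-million values as deposited, and log2 fold changes come from limma on log2(value + 1).

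Globin transcripts made up most of each library's per-million values. The erythroid share of recovered reads was smaller: in ABPC_EV replicate 2, 8.09 M of 11.73 M reads lay outside the erythroid list. HBB, HBA and HBA1, which encode chains of adult hemoglobin, together took 89.7% ± 2.57 of the per-million values under PBS, 84.2% ± 3.01 under FBMSC_EV and 76.2% ± 5.82 under ABPC_EV (SD, n = 3 each). All ABPC_EV and all FBMSC_EV libraries lay below all PBS libraries (exact permutation p = 0.1 for each, the smallest that 3 against 3 allow). ABPC_EV against FBMSC_EV gave an exact permutation p of 0.2. The 3 genes are close copies of other globin genes, so reads may have been divided among them. The share left for genes outside the erythroid list was 9.88% ± 2.51 under PBS, 15.4% ± 2.93 under FBMSC_EV and 23.4% ± 5.86 under ABPC_EV (SD, n = 3 each), 2.37 times as much under ABPC_EV as under PBS. Genes with a per-million value of at least 1 numbered 6765 ± 1539 under PBS, 9232 ± 388 under FBMSC_EV and 11249 ± 649 under ABPC_EV (SD, n = 3 each; exact permutation p = 0.1 for each pair).

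**Figure D1:**
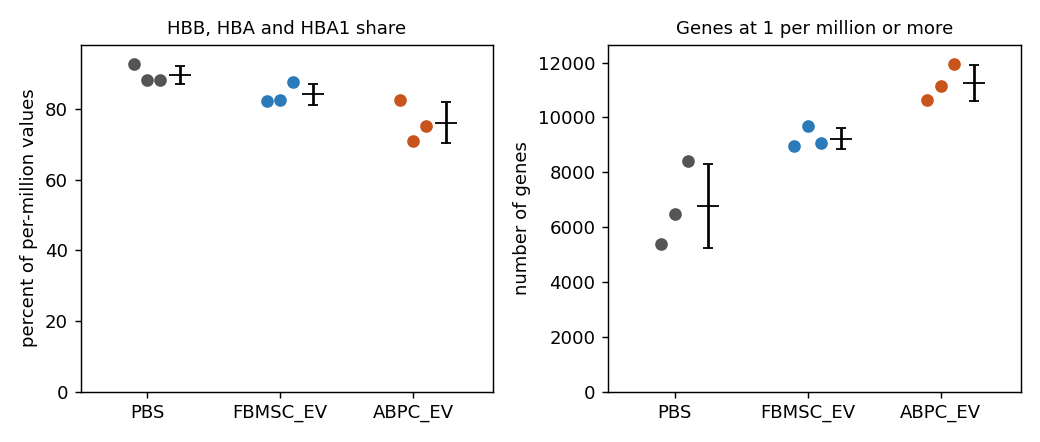
Left, the share of HBB, HBA and HBA1 in percent of each library's per-million values; right, the number of genes with a value of at least 1. Points are libraries and bars the mean ± SD of 3; the ABPC_EV group has the lowest mean globin share, 76.2%, although ABPC_EV replicate 1 (82.4%) lies above FBMSC_EV replicate 1 (82.3%), and the highest mean number of genes, 11249.

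The first comparison asks how blood RNA differed between animals given ABPC_EV and vehicle. Erythroid transcripts were lower under ABPC_EV relative to other genes (camera adjusted p = 0.0291 with an estimated correlation). That call held in 2 of 9 fits with each library left out. Transcripts of T cell genes were higher with the preset correlation, but not past the threshold with an estimated one (adjusted p = 0.976). HBG2, a fetal gamma-globin gene, fell by 4.04 on the log2 scale (SE 0.70, adjusted p = 0.000417), from 553 ± 624 under PBS to 24.0 ± 21.0 (SD, n = 3 each). CCL3, a chemokine of activated leukocytes, rose by 2.84 (SE 0.38, adjusted p = 0.000156), from 0.0545 ± 0.0944 to 7.75 ± 4.95 (SD, n = 3 each). Almost every tested gene was listed higher under ABPC_EV: the median log2 fold change over 10596 genes was 1.41, against a lower globin share of a fixed total.

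By limma, 9633 genes rose and 6 fell (99.94% of calls higher). The filter was applied to values as deposited, and fewer genes reached 1 under PBS (6765 on average) than under ABPC_EV (11249). A gene that reached 1 only in the ABPC_EV libraries was therefore tested, which favours rises, and such genes were not counted. After median-ratio scaling, which sets the median to 0.00, 0 genes passed (1080 at an unadjusted p under 0.05, 326 higher and 754 lower). By limma-voom on recovered reads with that scaling, 14 rose and 228 fell (5.79% higher; 2507 at an unadjusted p under 0.05). Of these, 64 also passed as deposited, 45 of them in the opposite direction. Counts after scaling depended on the tool as well: when count models were tried on the recovered reads, DESeq2 called genes in each of the 3 comparisons and edgeR with TMM called 0 in each. With the erythroid list taken out and the remainder rescaled to the same total, 0 passed (4497 at an unadjusted p under 0.05) and the median was 0.75. Libraries of the groups did not overlap for 85.5% of genes as deposited and for 14% after scaling, where chance gives 10%. The direction of a gene in this comparison therefore depends on the scale, and values relative to the all-gene median, or after scaling, stand beside those as deposited below. These 2 measures are not interchangeable. Adding 1 before the log2 shrinks the change of a low value, but the same all-gene median is taken off every gene. Some lists differ in sign between the 2 measures. The counts after median-ratio scaling and on scaled recovered reads also depended on single libraries: without PBS replicate 3 they were 130 and 516. The count on recovered reads was 0 without PBS replicate 1 or ABPC_EV replicate 3, 3 without PBS replicate 2 or ABPC_EV replicate 1, 71 without ABPC_EV replicate 2, and 160 without FBMSC_EV replicate 3; the scaled count was 2 without PBS replicate 2 and 3 without ABPC_EV replicate 2.

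**Figure D2:**
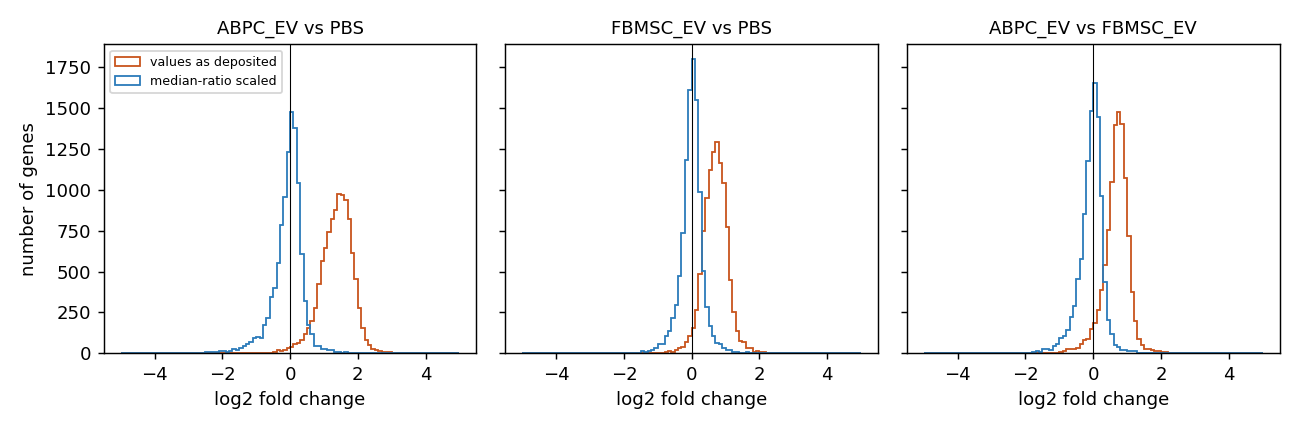
Histograms of log2 fold changes over 10596 genes for the 3 comparisons, as deposited (orange) and after median-ratio scaling (blue); the vertical line marks 0. As deposited the medians are 1.41, 0.70 and 0.71, and after scaling they lie at 0.00, 0.02 and -0.02.

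All 37 erythroid genes lay below the all-gene median, with a list median of -1.09 relative to it (camera adjusted p = 1.42e-46; adjusted p = 0.0291 with an estimated correlation). With each library left out in turn the estimated one held in 2 of 9 fits, without PBS replicate 3 or ABPC_EV replicate 3, and its adjusted p otherwise ranged from 0.0643 to 0.115; the preset one held in all 9. As deposited, the listed values of TFRC, EPB41, GYPC and RHAG rose, by log2 changes of 1.30, 1.14, 0.97 and 0.80. TFRC imports iron into erythroid cells, and the others encode red cell membrane proteins. They were 4 of 37 over all genes tested, and adjusted over the list alone 1 rose and 0 fell. After median-ratio scaling the list median was -1.44 and 27 of 37 fell, adjusted over the list alone, although over all genes 0 passed; the adjusted p of the scaled list was 0.362 with an estimated correlation. Scaled log2 changes were 0.10 for TFRC, -0.75 for EPB41, -0.82 for GYPC and -0.07 for RHAG. The adult globins and other red cell genes named here were chosen after their values were seen. HBB had a log2 change of -0.26 as deposited, -2.30 scaled and -2.56 on scaled recovered reads (limma-voom adjusted p = 0.0227). HBA had -0.25, -2.29 and -2.65, and HBA1 had 0.31, -1.73 and -2.24. ALAS2, the first enzyme of heme synthesis in red cells, had -0.06, -2.10 and -2.42, CA1, a red cell carbonic anhydrase, -0.75, -2.76 and -2.62, and BNIP3L, a mitophagy receptor of maturing red cells, -0.76, -2.80 and -2.76. All 6 passed on scaled recovered reads and none as deposited, and those calls depended on single libraries. None of the 6 passed without PBS replicate 1 (adjusted p from 0.175 to 0.499), PBS replicate 2 (0.101 to 0.376), ABPC_EV replicate 1 (0.058 to 0.279) or ABPC_EV replicate 3 (0.168 to 0.767). HBB (0.0654), ALAS2 (0.0626) and HBA1 (0.09) missed without ABPC_EV replicate 2, and HBA1 also without any 1 FBMSC_EV library (0.0594, 0.0569 and 0.0548). As deposited, log2 changes moved by over 1.5 times: BNIP3L to -0.29 and HBB to -0.16 without ABPC_EV replicate 2, CA1 to -1.18 (there adjusted p = 0.0333) and -0.43 without PBS replicates 1 and 2, and HBA1 to 0.49, 0.09 and 0.19 without PBS replicate 1, PBS replicate 3 and ABPC_EV replicate 2. ALAS2 moved to -0.17, 0.31 and -0.31 without PBS replicates 1, 2 and 3, and to -0.14, 0.00 and -0.03 without ABPC_EV replicates 1, 2 and 3. On scaled recovered reads HBA1 moved to -1.46 without PBS replicate 1. HBG2 had -5.96 scaled and -6.02 on scaled recovered reads (limma-voom adjusted p = 0.0113), and missed the threshold there without PBS replicate 1 (0.206) or ABPC_EV replicate 3 (0.168).

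T cell genes lay above the all-gene median in 24 of 26 cases, with a list median of 0.72 relative to it (camera adjusted p = 0.00561; adjusted p = 0.976 with an estimated correlation). As deposited all 26 rose, over all genes and adjusted over the list alone, but so did 9633 of all 10596 genes tested. After scaling the median was 0.40 and 0 members passed. The list missed the threshold without PBS replicate 3 (adjusted p = 0.558) or ABPC_EV replicate 3 (0.0705, with a relative median of 0.47). CD96, a receptor of T and NK cells, rose from 0.399 ± 0.14 to 6.41 ± 4.46 (SD, n = 3 each), a log2 change of 2.25. The heat shock list was also higher (relative median 0.48, adjusted p = 0.0453; 0.976 with an estimated correlation), with 27 of 28 members past the threshold as deposited by either adjustment; HSPH1, a chaperone, rose by 2.33. Heat shock genes missed it without PBS replicate 2 (0.113) or 3 (0.256), ABPC_EV replicate 2 (0.0893) or 3 (0.223), or FBMSC_EV replicate 2 (0.0504). Other called genes with the smallest p were CCR3, an eosinophil chemokine receptor (2.85), ID2, an inhibitor of DNA-binding helix-loop-helix factors (2.90), LY9, a lymphocyte surface receptor (2.44), BST1, an ectoenzyme of myeloid cells (2.19), CHMP7, an ESCRT-III component (2.62), CLDN5, a tight junction protein (1.78), GK5 (2.10), KIAA1257 (2.22) and MIR590 (2.97). Reads at MIR590 may belong to its host gene. Scaled, these were 1.04, 1.10, 0.92, 0.79, 0.86, 0.60, 0.84, 0.95 and 1.61, and CCL3 was 1.98. On scaled recovered reads CCL3 (3.98, limma-voom adjusted p = 0.0385) and KIAA1257 (1.66, adjusted p = 0.0228) passed, as did RORA, a nuclear receptor of lymphocytes named after its values were seen (2.13 as deposited, 2.27 on scaled reads, adjusted p = 0.0402). Those 3 calls each ended without PBS replicate 1 (adjusted p from 0.294 to 0.426), PBS replicate 2 (0.183 to 0.266), ABPC_EV replicate 1 (0.0848 to 0.247) or ABPC_EV replicate 3 (0.392 to 0.591, with RORA at 1.13). KIAA1257 (0.0598) and RORA (0.0626) also missed without ABPC_EV replicate 2, RORA without FBMSC_EV replicates 2 (0.0576) and 3 (0.0564), and CCL3 without PBS replicate 3 (0.0646) or any 1 FBMSC_EV library (0.0515, 0.0548 and 0.0548).

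The other 6 lists that passed were lower relative to the median. Relative medians were -0.20 for ribosomal protein (adjusted p = 4.63e-10), -0.15 for mitochondrial genome (5.05e-08), -0.25 for neutrophil (2.30e-07), -0.19 for antioxidant (5.60e-05) and -0.45 for immature granule neutrophil (0.00135). Oxidative phosphorylation had a median of 0.00 and a mean of -0.09, so its median and test differ in sign (adjusted p = 0.00803). With an estimated correlation the mitochondrial list held (adjusted p = 0.0434), but with each library left out only in 1 of 9 fits, without PBS replicate 3 (up to 0.382 in the others), and the other 5 had 0.976. Without PBS replicate 2 the neutrophil (0.264), granule (0.614, with a relative median of 0.13) and oxidative phosphorylation lists (0.066) missed the threshold. The last also missed it without PBS replicate 3 (0.157) or ABPC_EV replicate 2 (0.0893), the ribosomal list without ABPC_EV replicate 2 (0.231) and the granule list without ABPC_EV replicate 3 (0.0568).

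Single libraries moved these 6 relative medians by over 1.5 times, some to about 0. For neutrophil genes they were -0.01 and -0.53 without PBS replicates 2 and 3, and -0.02, -0.62 and 0.01 without ABPC_EV replicates 1, 2 and 3. For antioxidant genes they were -0.03 without PBS replicate 2, and -0.32 and -0.05 without ABPC_EV replicates 2 and 3. For the mitochondrial list they were -0.40, -0.40 and -0.02 without PBS replicates 1, 2 and 3, and -0.30, -0.24 and -0.32 without ABPC_EV replicates 1, 2 and 3. For ribosomal genes they were -0.37 and -0.07 without PBS replicates 1 and 2, and -0.52 and 0.11 without ABPC_EV replicates 1 and 2. Granule genes had -0.81 without PBS replicate 3 and -0.11 without ABPC_EV replicate 3. Oxidative phosphorylation had -0.10, 0.10 and 0.07 without PBS replicates 1, 2 and 3, and -0.01, 0.07 and 0.02 without ABPC_EV replicates 1, 2 and 3.

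After scaling, most changes in these lists were negative: 74 of 77 ribosomal, 23 of 25 neutrophil, 25 of 27 antioxidant and 45 of 56 oxidative phosphorylation genes. As deposited, where 9633 of all 10596 genes rose, 52, 15, 19 and 44 of them rose over all genes tested, and 46, 15, 18 and 44 adjusted over the list alone. In the granule list 4 of 8 rose by either adjustment: BPI, an antibacterial granule protein (0.97), and, named after their values were seen, RETN (1.49), AZU1 (0.95) and LTF (1.32). In the mitochondrial list 5 of 11 rose by either adjustment: ND5 (1.35), and, named after their values were seen, ND2 (1.97), CYTB (1.96), ND1 (1.59) and COX2 (1.44). ATP6 (-0.61), ND3 (0.95) and ND4 (1.26) did not pass, and moved by over 1.5 times: ATP6 to -0.92, -0.92 and 0.00 without PBS replicates 1, 2 and 3 (adjusted p = 0.0491, 0.0295 and 1), ND4 to 0.72 and 1.91 without PBS replicates 1 and 3 (0.283 and 0.0151), and ND3 to 1.51, 0.58 and 0.47 without PBS replicates 2 and 3 and ABPC_EV replicate 2 (0.00299, 0.353 and 0.281). These genes encode subunits of the respiratory chain or, for ATP6, of ATP synthase, and may share reads with nuclear copies. GLRX, a glutaredoxin, rose by 1.40, NAMPT, an enzyme of NAD synthesis, by 1.39, and CYCS, cytochrome c, by 1.41. After scaling, the mitochondrial, granule and heat shock lists no longer passed (adjusted p = 0.355, 0.491 and 0.614), and BPI, AZU1, LTF, GLRX, NAMPT, ND1, ND3 and ND4 turned lower. Cytotoxic and NK (scaled median 0.40, adjusted p = 0.000488), proteasome (-0.21, 0.000315) and autophagy genes (-0.28, 0.0266) passed only after it, and not with an estimated correlation (adjusted p = 0.808, 0.362 and 0.808). On scaled recovered reads these 3 passed too, and interferon-stimulated, glycolysis and platelet genes passed as well, as lower (adjusted p = 0.049, 0.0492 and 0.0492); after scaling of the deposited values they had 0.404, 0.416 and 0.833.

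The remaining 20 lists did not pass as deposited. Relative medians were 0.65 for cytotoxic and NK genes (adjusted p = 0.11) and -0.17 for cell cycle genes (0.655). The others were B cell (-0.03, adjusted p = 0.655), dendritic cell (-0.16, 0.655), eosinophil and basophil (-0.16, 0.655), monocyte (0.37, 0.887), plasma cell (0.27, 0.776), platelet (0.07, 0.887), interferon-stimulated (0.12, 0.776), inflammation (0.16, 0.655), MHC class II (0.20, 0.507), senescence (0.25, 0.776), DNA repair (-0.17, 0.921), autophagy (-0.02, 0.507), proteasome (0.15, 0.887), glycolysis (0.22, 0.803), cholesterol (0.02, 0.52), immediate early (0.29, 0.921), regulatory T cell (0.16, 0.823) and matrix and bone (0.10, 0.34). In 7 of these lists median and test differ in sign: cell cycle, eosinophil and basophil, and DNA repair were higher in the test, and platelet, interferon-stimulated, MHC class II and immediate early lower. After median-ratio scaling, relative medians turned negative for proteasome (-0.21), MHC class II (-0.14), glycolysis (-0.13), interferon-stimulated (-0.12) and inflammation genes (-0.12). So did those of immediate early (-0.10), platelet (-0.06), plasma cell (-0.04) and senescence genes (-0.01). They turned positive for eosinophil and basophil (0.23), cell cycle (0.11), dendritic cell (0.05) and DNA repair genes (0.02). The other lists that did not pass kept their sign. The member named for a list lies on the side of the test as deposited. USP18 (-0.16 relative to the all-gene median), CD80 (-0.03), PRKAR2B (-0.02) and NR4A2 (-0.01) thus lie below it there. After median-ratio scaling their log2 changes were 0.44, 0.30, 0.22 and 0.54, above the scaled all-gene median of 0.00. Each of these leading members passed as deposited: PRF1, which forms pores in target cells (3.38), CDKN1C (2.92), CCL5 (2.41), ACLY (2.28), HMGB2 (2.06), PRDM1 (2.01), TOX (1.99), PSMB2 (1.98), HK1 (1.95), TERF1 (1.77), NR4A2 (1.40), CR2 (1.40), PRKAR2B (1.40), CD80 (1.38), ATG14 (1.26), USP18 (1.26), CLNK (1.23) and CCL3, CCR3 and ID2 above. Without PBS replicate 1 or ABPC_EV replicate 3, 6 of the 48 named genes that passed missed the threshold each time (adjusted p up to 0.133 and 0.154); 4 did without PBS replicate 2 (up to 0.0944), 3 without ABPC_EV replicate 1 (up to 0.0851), 2 without PBS replicate 3 (up to 0.27) and 1 without ABPC_EV replicate 2 (0.11). They were AZU1, BPI, CD80, COX2, CYTB, EPB41, GYPC, LTF, ND1 and RHAG. Among the named genes that passed, log2 changes as deposited that moved by over 1.5 times were LTF (2.13 without PBS replicate 2 and 0.74 without PBS replicate 3), ND1 (1.02) and ND5 (0.90) without PBS replicate 2, AZU1 without PBS replicate 1 or ABPC_EV replicate 2 (0.63 each), ND2 without ABPC_EV replicate 2 (1.23), and CD80 (0.82), COX2 (0.90) and ND1 (1.05) without ABPC_EV replicate 3.

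The second comparison asks the same of FBMSC_EV against vehicle. With the preset correlation, interferon-stimulated and monocyte genes were higher relative to other genes, and B cell and platelet genes lower. With an estimated correlation none of these 4 lists passed (adjusted p = 0.118, 0.554, 0.508 and 0.508). MX1, an antiviral GTPase, rose by 2.13 (SE 0.42, adjusted p = 0.0228), from 4.69 ± 2.42 to 23.6 ± 9.97 (SD, n = 3 each). IFIT2 rose by 2.20 (adjusted p = 0.0209) and IFI44 by 2.04 (adjusted p = 0.0279), both interferon-induced. HBG2 fell by 3.43 (SE 0.70, adjusted p = 0.0279), from 553 ± 624 to 29.2 ± 8.59 (SD, n = 3 each). By limma 27 genes rose and 1, HBG2, fell (96.43% higher), with 4637 at an unadjusted p under 0.05 and an all-gene median of 0.70. After median-ratio scaling 0 passed (512 at an unadjusted p under 0.05), and on scaled recovered reads 0 passed by limma-voom (879), although DESeq2, when tried on these reads, called some genes. With the erythroid list taken out 0 passed (1170), with a median of 0.42. Libraries did not overlap for 51% of genes as deposited and 9.7% after scaling, where chance gives 10%.

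Interferon-stimulated genes lay above the all-gene median in 38 of 40 cases, with a list median of 0.79 relative to it (camera adjusted p = 2.72e-20; adjusted p = 0.118 with an estimated correlation). Over all genes tested 5 of 40 rose, and adjusted over the list alone 37 did. They were MX1, IFIT2 and IFI44, and, named after their values were seen, PARP9 (1.68) and ISG15 (1.63). After scaling the median was 0.66 and 0 members passed. Monocyte genes had a relative median of 0.66 (adjusted p = 1.72e-05; 0.554 with an estimated correlation) and 0 of 23 members past the threshold over all genes, 16 adjusted over the list alone; CD163, a scavenger receptor, had 18.8 ± 10.9 against 4.25 ± 2.71 (SD, n = 3 each; limma adjusted p = 0.0671). Cytotoxic and NK genes had 0.49 (adjusted p = 0.00015; 0.936 with an estimated correlation; 0 of 26 over all genes, 15 adjusted over the list alone), with PRF1 at 2.16 (adjusted p = 0.0699). Inflammation genes had 0.31 (adjusted p = 0.000327; 0.878 with an estimated correlation; 0 of 31 over all genes, 22 adjusted over the list alone), with IL18RAP at 1.25, but did not pass on scaled recovered reads (adjusted p = 0.47). Proteasome (0.26, adjusted p = 0.0063; 0 of 37 over all genes, 24 adjusted over the list alone) and heat shock (0.23, adjusted p = 0.0131; 0 of 28 and 21) were higher as well, each with 0.936 with an estimated correlation, and neither passed after scaling (adjusted p = 0.9 and 0.647). PSME2 (1.61) and DNAJA1 (1.34) led them without passing. After scaling, 0 members of the monocyte, cytotoxic and NK, inflammation, proteasome and heat shock lists passed, adjusted over the list alone. Without PBS replicate 3 the monocyte (adjusted p = 0.165), cytotoxic and NK (0.857), inflammation (0.509) and heat shock lists (0.0761) missed the threshold. Without FBMSC_EV replicate 2 the cytotoxic and NK (0.165), proteasome (0.0836) and heat shock lists (0.117) did, and inflammation did without FBMSC_EV replicate 1 (0.19). Heat shock also missed it without PBS replicate 2 (0.0989), and proteasome without PBS replicate 1 (0.0678) or FBMSC_EV replicate 3 (0.0782). Relative medians that moved by over 1.5 times were cytotoxic and NK without FBMSC_EV replicates 2 and 3 (0.24 and 0.75), inflammation without PBS replicate 3 (0.16) and FBMSC_EV replicates 1 and 3 (0.14 and 0.49), and proteasome without PBS replicate 1 (0.14) and FBMSC_EV replicate 2 (0.17).

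B cell genes lay below the all-gene median in 20 of 20 cases (relative median -0.56, adjusted p = 2.63e-13; 0.508 with an estimated correlation), and 0 members passed by either adjustment. FCRLA, a B cell protein, had 2.92 ± 1.81 against 4.98 ± 2.89 (SD, n = 3 each). Its log2 change of -0.59 (adjusted p = 0.224) moved to -0.92 and -0.23 without PBS replicates 1 and 3, and to -0.36 and -0.95 without FBMSC_EV replicates 1 and 3. Platelet genes had -0.52 (adjusted p = 4.25e-11; 0.508 with an estimated correlation), erythroid genes -0.24 (4.00e-06; 0.508) and ribosomal genes -0.04 (0.000327; 0.936), with 0 members past the threshold by either adjustment; PRKAR2B (0.45), TFRC (0.58) and FAU (0.66), their leading members, did not pass. The erythroid list missed the threshold without PBS replicate 1 (0.0624) or 2 (0.0546), and the ribosomal list without PBS replicate 2 (0.562). Relative medians moved by over 1.5 times: B cell to -0.36 without PBS replicate 3, and -0.33 and -0.92 without FBMSC_EV replicates 1 and 3. The erythroid one moved to -0.04, -0.07 and -0.58 without PBS replicates 1, 2 and 3. The ribosomal one moved to -0.21, 0.12 and -0.02 without these, and to 0.03 and -0.12 without FBMSC_EV replicates 1 and 3. The mitochondrial list had -0.39 (adjusted p = 1.32e-05; 0.118 with an estimated correlation) and did not pass after scaling (adjusted p = 0.328). Its 1 member past the threshold by either adjustment, ATP6, named after its values were seen, rose by 1.82, and COX3 had -1.42 (adjusted p = 0.0937), but -2.17 without PBS replicate 2 (0.0396) and -0.80 without FBMSC_EV replicate 3. PRKAR2B had 0.27 without PBS replicate 2 or FBMSC_EV replicate 1. Further called genes were ALDH1A1, a retinal dehydrogenase (2.03, adjusted p = 0.0116), S100P, a calcium-binding protein (2.27), SERPINB10 (1.67), CNIH4 (1.84) and MIR616 (1.80). MIR186 and MIR657 also passed; both are listed at 0 in all PBS libraries and at 2.73 ± 1.25 and 3.32 ± 1.69 (SD, n = 3 each) under FBMSC_EV, and reads at these MIR genes may belong to their host genes. Scaled log2 changes were 1.19 for MX1, 1.24 for IFIT2, 1.20 for IFI44, 1.19 for ALDH1A1 and -4.51 for HBG2.

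Of the other lists, 18 did not pass. Relative medians were 0.38 for neutrophil (adjusted p = 0.268), -0.05 for immature granule neutrophil (0.193), -0.13 for eosinophil and basophil (0.962), 0.26 for T cell (0.782), -0.19 for plasma cell (0.105), -0.17 for dendritic cell (0.782), 0.11 for oxidative phosphorylation (0.962), 0.06 for antioxidant (0.578), 0.14 for autophagy (0.295), 0.11 for MHC class II (0.578), -0.06 for regulatory T cell (0.329), 0.24 for immediate early (0.268), 0.24 for senescence (0.193), -0.16 for DNA repair (0.329), -0.17 for cell cycle (0.39), 0.07 for cholesterol (0.319), 0.26 for glycolysis (0.267) and 0.12 for matrix and bone (0.573). In 5 of them median and test differ in sign: T cell, oxidative phosphorylation, antioxidant and MHC class II were lower in the test, and eosinophil and basophil higher. After scaling, relative medians turned negative for antioxidant (-0.19), MHC class II (-0.14), oxidative phosphorylation (-0.12), glycolysis (-0.02) and T cell genes (-0.0037). That of eosinophil and basophil genes turned positive (0.10). The members named for the 5 lists follow the test. As deposited, THEMIS (-0.13 relative to the all-gene median), PRDX1 (-0.04), RFXANK (-0.03) and NDUFB3 (-0.01) thus lie below it. Scaled log2 changes were 0.23 for THEMIS and 0.20 for NDUFB3, above the scaled all-gene median of 0.02. RFXANK had 0.02, about that median, and PRDX1 had -0.24. After scaling, plasma cell (-0.23, adjusted p = 0.00266), oxidative phosphorylation (-0.10, 0.00299) and antioxidant genes (-0.17, 0.0457) passed, but not with an estimated correlation (adjusted p = 0.521, 0.521 and 0.8). None of the leading members of these lists passed as deposited: STEAP4 (1.94), FN1 (1.76), HK3 (1.65), CXCL8 (1.64), CCR3 (1.53), GABARAPL1 (1.34), KLF4 (1.13), IDI1 (1.03), POLB (0.69), NDUFB3 (0.69), RFXANK (0.67), MCM3 (0.67), PRDX1 (0.67), CLEC10A (0.60), FKBP11 (0.59), THEMIS (0.58), AZU1 (0.56) and IKZF2 (0.42). Without PBS replicate 1, NDUFB3 (0.46), RFXANK (0.42) and AZU1 (0.23) moved by over 1.5 times, and without FBMSC_EV replicate 1 CLEC10A did (0.36). The count of genes leaned on single libraries: it was 13 without PBS replicate 1, 4526 without PBS replicate 3, 73, 51 and 93 without FBMSC_EV replicates 1, 2 and 3, and 119 and 460 without ABPC_EV replicates 1 and 2. Of the 14 named genes that passed, HBG2, ATP6, CNIH4, MIR616, PARP9, S100P and SERPINB10 missed the threshold without PBS replicate 1 (adjusted p up to 0.223), ATP6, IFI44, IFIT2, MX1, PARP9 and SERPINB10 without PBS replicate 2 (up to 0.134), IFI44, MX1 and PARP9 without FBMSC_EV replicate 1 (up to 0.0605), CNIH4 and ISG15 without FBMSC_EV replicate 2 (up to 0.0654), and PARP9 without FBMSC_EV replicate 3 (0.0542).

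**Figure D3:**
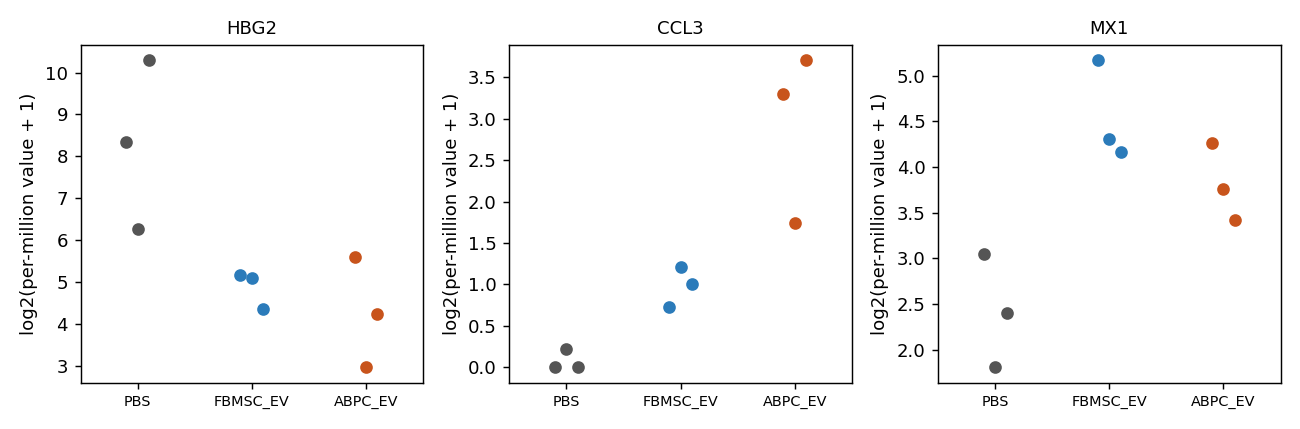
log2(per-million value + 1) of HBG2, CCL3 and MX1 in each of the 9 libraries, as deposited; each point is a library. HBG2 is 553 on average under PBS and 24.0 under ABPC_EV, CCL3 0.0545 and 7.75, and MX1 4.69 under PBS and 23.6 under FBMSC_EV.

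The third comparison sets the EV preparations against each other. Erythroid and interferon-stimulated genes were lower under ABPC_EV than under FBMSC_EV relative to other genes (adjusted p = 0.0464 each with an estimated correlation, and from 0.0607 to 0.26 with any 1 of the 9 libraries left out). With the preset correlation platelet, B cell and T cell genes were higher and neutrophil genes lower, but none of these 4 lists passed with an estimated one (adjusted p = 0.817, 0.817, 0.857 and 0.549). CLDN5 rose by 1.96 (SE 0.28, adjusted p = 0.00105), from 0.292 ± 0.0958 to 4.11 ± 1.03 (SD, n = 3 each). CAVIN2, a caveolar protein abundant in platelets, rose by 1.95 (adjusted p = 0.00825), THBS1, a protein of platelet granules, by 1.89 (0.00825) and VWF, which binds platelets to vessel walls, by 1.52 (0.0135). By limma 62 genes rose and 6 fell (91.18% higher), with 5120 at an unadjusted p under 0.05 and an all-gene median of 0.71. After median-ratio scaling 0 passed (568 at an unadjusted p under 0.05), on scaled recovered reads by limma-voom 0 (1250), although DESeq2, when tried on these reads, called some, and with the erythroid list taken out 0 (536; median 0.32). Libraries did not overlap for 50.6% of genes as deposited and 11% after scaling, where chance gives 10%.

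Erythroid genes lay below the all-gene median in 36 of 37 cases (relative median -0.86, camera adjusted p = 5.01e-31; 0.0464 with an estimated correlation). HEMGN, a nuclear protein of erythroid cells, had 24.2 ± 11.2 against 53.4 ± 6.76 (SD, n = 3 each; log2 change -1.22, but -0.78 without ABPC_EV replicate 2), and CA2 and SELENBP1 had log2 changes of -0.65 and -0.94. Interferon-stimulated genes lay below it in 39 of 40 cases (relative median -0.62, adjusted p = 1.50e-23; 0.0464 with an estimated correlation). RSAD2, an antiviral enzyme, had 3.65 ± 0.927 against 7.06 ± 2.34 (SD, n = 3 each), and CMPK2, IFI44 and USP18 had -0.74, -0.85 and 0.70. Each moved by over 1.5 times without single libraries: CMPK2 had -1.13 and -0.38 without FBMSC_EV replicate 1 and ABPC_EV replicate 2, IFI44 -0.49 without FBMSC_EV replicate 1, and USP18 0.30 without ABPC_EV replicate 3. In both lists 0 members passed by either adjustment. Scaled medians were -0.97 and -0.76, with adjusted p = 0.434 and 0.362 with an estimated correlation. The scaled interferon level differed by -0.77 (SE 0.163, n = 3 each), and the interferon level minus the monocyte level by -0.39 (SE 0.315). The interferon list also passed in 6 of the 9 other splits of these 6 libraries, with relative medians up to 0.56 in size. Neutrophil genes lay below the median in 25 of 25 cases (-0.62, adjusted p = 8.54e-15; 0.549 with an estimated correlation), with 0 members past the threshold by either adjustment; TNFAIP6 had -0.91 (adjusted p = 0.103), and -0.54 without FBMSC_EV replicate 1. The neutrophil list passed with each library left out, but its relative median was -0.18 without FBMSC_EV replicate 1, and -0.39, -1.001 and -0.30 without ABPC_EV replicates 1, 2 and 3.

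Platelet genes had a relative median of 0.51 (adjusted p = 1.19e-05; 0.817 with an estimated correlation), with 4 of 23 members past the threshold over all genes and 19 adjusted over the list alone: CLDN5 and CAVIN2, and, named after their values were seen, PF4V1 (2.11) and GP6 (1.12). B cell genes had 0.58 (adjusted p = 9.16e-06; 0.817 with an estimated correlation), with 4 of 20 over all genes and 18 adjusted over the list alone: CXCR5, a follicle-homing receptor (1.90), and, named after their values were seen, FCRL1 (1.95), FCRL2 (1.51) and FCER2 (1.45). T cell genes had 0.56 (adjusted p = 0.000114; 0.857 with an estimated correlation), with 3 of 26 over all genes and 21 adjusted over the list alone: CCR7, a lymph node homing receptor (2.12), and, named after their values were seen, CD4 (1.72) and LEF1 (1.62). Plasma cell genes had 0.50 (adjusted p = 0.0403, and 0.857 with an estimated correlation), with 0 of 13 over all genes and 10 adjusted over the list alone. DERL3 had 1.23. These counts stand beside a shift of all genes: as deposited, 5091 of 10596 were higher at an unadjusted limma p under 0.05. After scaling, adjusted over the list alone, 3 platelet members rose, and 0 did in the B cell, T cell and plasma cell lists. On scaled recovered reads the B cell (adjusted p = 0.0972) and plasma cell lists (0.0528) did not pass. The platelet list missed the threshold without ABPC_EV replicate 2 (adjusted p = 0.071), B cell without ABPC_EV replicate 1 (0.0979) and T cell without ABPC_EV replicate 3 (0.0696). Plasma cell missed it without ABPC_EV replicate 1 (0.0734) or 3 (0.0853), FBMSC_EV replicate 1 (0.152) or 3 (0.057), or PBS replicate 3 (0.0576). Relative medians moved by over 1.5 times for platelet (0.33 without FBMSC_EV replicate 3, 0.09 and 0.89 without ABPC_EV replicates 2 and 3) and B cell genes (0.33 without FBMSC_EV replicate 1, 0.34 and 0.92 without ABPC_EV replicates 1 and 3). T cell genes had 0.29 and 0.24 without FBMSC_EV replicate 1 and ABPC_EV replicate 3, and plasma cell genes 0.33 and 0.32 without ABPC_EV replicates 1 and 2. Outside these lists EGFL7 (2.07), CCL3 (1.93), CHMP7 (1.91), NT5DC3 (1.23), XRCC2 (1.68) and TRNAT-AGU (2.03, whose reads cannot be placed on 1 tRNA gene) rose. DEFB1, a defensin, fell by 1.45 (adjusted p = 0.0289) and MIR657 fell by 1.67. ATP6 was lower too, listed at 0 in all ABPC_EV libraries and at 4.56 ± 1.58 (SD, n = 3) under FBMSC_EV. Scaled log2 changes were 1.24 for CLDN5, 1.07 for CAVIN2, 1.05 for THBS1, 0.80 for VWF and -1.62 for DEFB1.

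The 9 other lists that passed were lower in the test: monocyte (relative median -0.25, adjusted p = 0.000226), antioxidant (-0.40, 2.47e-05), ribosomal (-0.12, 2.47e-05), oxidative phosphorylation (-0.08, 0.0015), immature granule neutrophil (-0.40, 0.0127), mitochondrial genome (0.54, with a mean of -0.05, so that median and test differ in sign; 0.0214), autophagy (-0.12, 0.0237), proteasome (-0.16, 0.0258) and inflammation (-0.19, 0.0303). With an estimated correlation their adjusted p lay between 0.549 and 0.857. The mitochondrial, granule and inflammation lists did not pass after scaling (adjusted p = 0.975, 0.487 and 0.0535), and these 3 (0.712, 0.865 and 0.0578) and the monocyte list (0.0607) did not on scaled recovered reads. Past the threshold over all genes were ATP6 in the mitochondrial list and CCL3 in the inflammation list, and 0 in the other 7; adjusted over the list alone 6 mitochondrial members were higher and 1 lower, 1 inflammation member was higher and 0 in the other 7. Their leading members TXN (-0.89), RPL22 (0.69), CYCS (0.61), TCF7L2 (0.53), RETN (0.61), BNIP3 (0.66), PSMD6 (0.68) and TNF (0.71) did not pass. TXN had -0.46 without ABPC_EV replicate 2, TCF7L2 0.31, 0.88 and 0.33 without FBMSC_EV replicates 1 and 2 and ABPC_EV replicate 2, and RETN 1.04 and 0.29 without FBMSC_EV replicates 1 and 2. Without FBMSC_EV replicate 1 the monocyte (adjusted p = 0.12), granule (0.37), mitochondrial (0.415), autophagy (0.213) and inflammation lists (0.855) missed the threshold. Without ABPC_EV replicate 3 granule (0.298), mitochondrial (0.0853), autophagy (0.0853) and inflammation (0.179) did, without ABPC_EV replicate 1 autophagy (0.143), proteasome (0.0803) and inflammation (0.222), and without ABPC_EV replicate 2 ribosomal (0.909), mitochondrial (0.139) and proteasome (0.071). Without PBS replicate 2 granule (0.0541), mitochondrial (0.228) and inflammation (0.0553) did. Without FBMSC_EV replicate 3 mitochondrial (0.143) and proteasome (0.0866) did, and proteasome also without FBMSC_EV replicate 2 (0.0772) or PBS replicate 1 (0.055).

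Single libraries also moved these 9 relative medians by over 1.5 times. Without FBMSC_EV replicate 1 they were -0.13 for monocyte, -0.16 for antioxidant, -0.22 for ribosomal, 0.01 for granule, -0.04 for autophagy and -0.02 for inflammation genes. Without FBMSC_EV replicate 2 they were -0.05 for oxidative phosphorylation, -0.69 for granule, 0.35 for mitochondrial and -0.20 for autophagy genes, and without FBMSC_EV replicate 3 -0.50 for monocyte, -0.05 for ribosomal, 0.24 for mitochondrial and -0.18 for autophagy genes. Without ABPC_EV replicate 1 they were -0.11 for monocyte, -0.36 for ribosomal, -0.01 for oxidative phosphorylation, -0.06 for autophagy, -0.09 for proteasome and -0.10 for inflammation genes. Without ABPC_EV replicate 2 they were -0.61 for antioxidant, 0.11 for ribosomal, -0.14 for oxidative phosphorylation, -0.63 for granule, 0.19 for mitochondrial, -0.25 for autophagy and -0.40 for inflammation genes. Without ABPC_EV replicate 3 they were -0.21 for antioxidant, -0.18 for granule, 0.28 for mitochondrial and -0.06 for autophagy genes.

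Among lists that did not pass, relative medians were 0.13 for cytotoxic and NK (adjusted p = 0.417), 0.02 for eosinophil and basophil (0.421), 0.11 for dendritic cell (0.396), 0.10 for heat shock (0.47), 0.07 for MHC class II (0.421), 0.16 for regulatory T cell (0.305), 0.00 for immediate early (0.23), -0.08 for senescence (0.417), 0.02 for DNA repair (0.323), 0.07 for cell cycle (0.13), 0.01 for cholesterol (0.799), -0.04 for glycolysis (0.417) and 0.11 for matrix and bone (0.335). In 4 of them, cytotoxic and NK, dendritic cell, MHC class II and immediate early, the median is positive and the test lower, and the members named (FASLG, CLEC10A, CD80 and NR4A1) follow the test. EPX (2.15), ICOS (1.33), HSPH1 (1.21), ATM (1.21), BMP6 (1.16), MSMO1 (1.16), AURKB (1.08), CD80 (0.71), NR4A1 (0.68), BNIP3 (0.66), CLEC10A (0.58) and FASLG (0.57) were leading members of these lists, and none of those named passed. Some moved by over 1.5 times, without FBMSC_EV replicate 1 (EPX 1.43, CD80 0.24 and NR4A1 0.41), FBMSC_EV replicate 2 (CLEC10A 0.30 and FASLG 0.96), FBMSC_EV replicate 3 (FASLG 0.26), ABPC_EV replicate 1 (CLEC10A 1.03, there adjusted p = 0.0304), ABPC_EV replicate 2 (CD80 1.065 and CLEC10A 0.27) and ABPC_EV replicate 3 (CD80 0.15 and FASLG 0.21). The count of genes was 45 without ABPC_EV replicate 3, 4863 and 372 without ABPC_EV replicates 1 and 2, 284 without FBMSC_EV replicate 2, and 164 and 2512 without PBS replicates 2 and 3. The count of lists was 10 without FBMSC_EV replicate 1 or ABPC_EV replicate 3. Of the 22 named genes that passed, 10 missed the threshold without FBMSC_EV replicate 3, THBS1 and VWF among them (adjusted p up to 0.136), 10 without ABPC_EV replicate 3, CCL3, CCR7 and CXCR5 among them (up to 0.186), 6 without FBMSC_EV replicate 1 (up to 0.152), 5 without PBS replicate 1 (up to 0.0684) and 2 without ABPC_EV replicate 2 (up to 0.0611).

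Fold changes against PBS under the 2 EV preparations were compared across genes, which are not independent replicates. Pearson's r was 0.623 and Spearman's rho 0.655 over 10596 genes, and 96.9% of genes had the same sign. The same PBS libraries enter both sides. For simulated unchanged groups (100 draws), whose shared PBS libraries were simulated as well, r averaged 0.455 (SD 0.42, highest 0.957) and the same-sign share 66.8% (highest 96.0%). The covariance was 0.107 against a simulated mean of 0.054 (highest 0.208), a difference of 0.053. After median-ratio scaling r was 0.623, the same-sign share 70.2% (simulated mean 66.1%) and the covariance 0.096 against 0.058, a difference of 0.038. Of 9633 and 27 genes that rose, 24 were shared, and of 6 and 1 that fell, 1 was shared, HBG2. Independent lists would share 24.5 and 0.001, but these lists have their PBS libraries in common, so neither number is the value for no change, and no overlap was simulated. With disjoint controls, 1 PBS library for one preparation and the other 2 for the other (6 ways), r ranged from 0.054 to 0.476 as deposited and from -0.148 to 0.346 after scaling, lower than with shared controls; a single control also adds noise.

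Levels of the lists per library, as mean log2(scaled value + 1), describe the makeup of blood RNA. Erythroid levels were 5.99 ± 0.73 under PBS, 5.49 ± 0.14 under FBMSC_EV and 4.55 ± 0.37 under ABPC_EV (SD, n = 3 each; exact permutation p = 0.1 for ABPC_EV against either other group and 0.4 for FBMSC_EV against PBS). Interferon levels were 2.92 ± 0.60, 3.51 ± 0.23 and 2.73 ± 0.16 in that order (SD, n = 3 each; exact permutation p = 0.2 for FBMSC_EV against PBS and 0.1 for ABPC_EV against FBMSC_EV), and PBS replicate 1, at 3.61, was as high as the FBMSC_EV libraries. T cell levels were 3.21 ± 0.20, 3.19 ± 0.36 and 3.58 ± 0.46 (SD, n = 3 each; exact permutation p = 0.3 for ABPC_EV against PBS). Monocyte levels were 3.43 ± 0.24, 3.87 ± 0.42 and 3.49 ± 0.06 (SD, n = 3 each; exact permutation p = 0.3 for FBMSC_EV against PBS). B cell levels were 3.04 ± 0.41, 2.39 ± 0.48 and 2.89 ± 0.54, and platelet levels 2.62 ± 0.15, 2.11 ± 0.40 and 2.56 ± 0.65 (SD, n = 3 each; exact permutation p = 0.3 and 0.2 for FBMSC_EV against PBS). For ABPC_EV against FBMSC_EV the libraries of platelet, B cell and T cell genes overlapped (exact permutation p = 0.4, 0.2 and 0.4), with ABPC_EV replicate 3 at 1.90 below FBMSC_EV replicate 1 at 2.55 for platelet genes. The smallest p that 3 against 3 allow is 0.1, so none of these could pass 0.05.

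**Figure D4:**
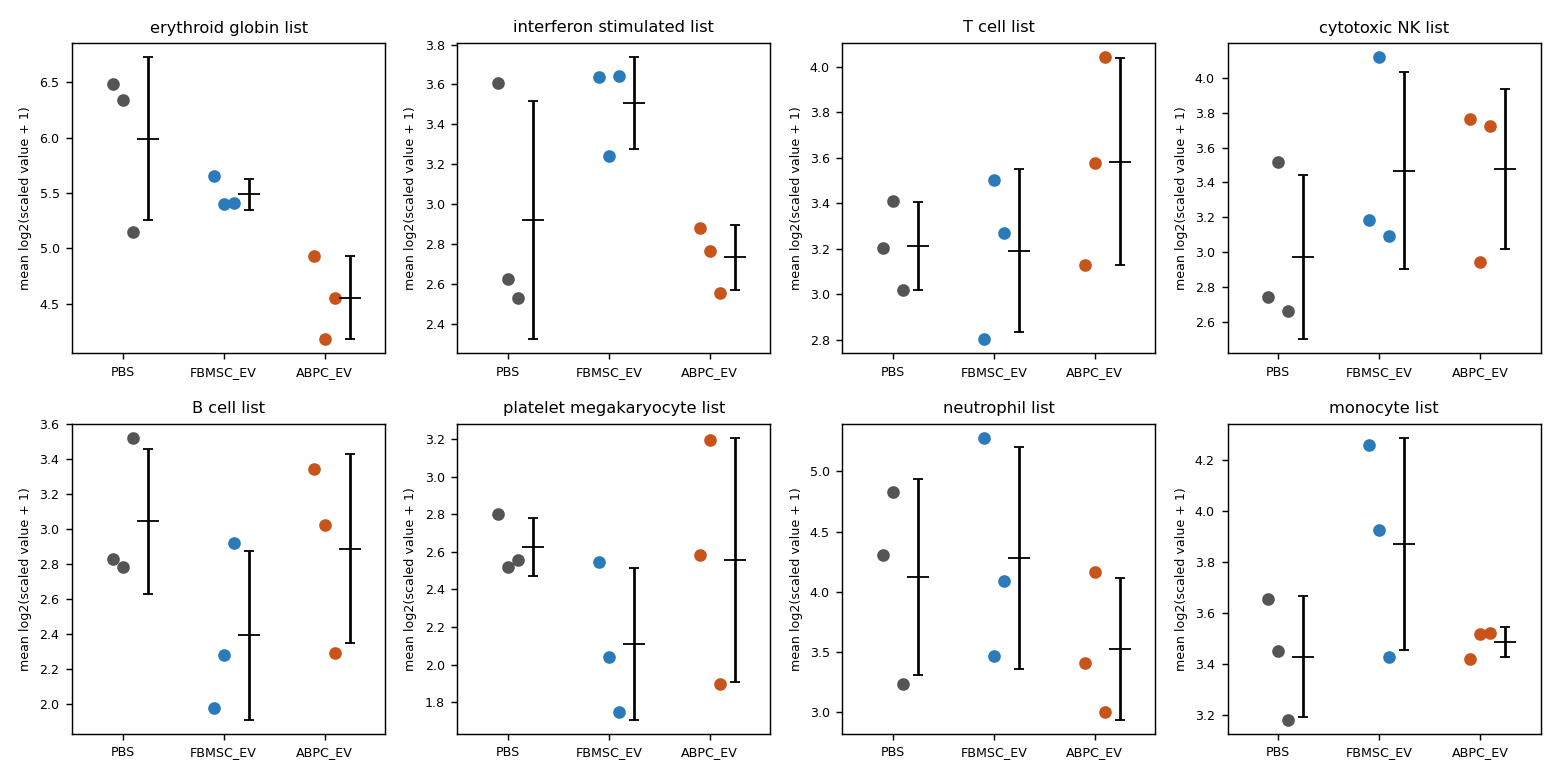
Mean log2(scaled value + 1) of 8 gene lists in each library after median-ratio scaling; points are libraries and bars the mean ± SD of 3, on axes that do not start at 0. Erythroid levels average 5.99 under PBS and 4.55 under ABPC_EV, and interferon levels 2.92 under PBS and 3.51 under FBMSC_EV.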

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

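The tests of the erythroid share, of depth, of monocyte RNA and of HBG2 were chosen after the results were seen; the test of the interferon genes with each library left out, and the counts over splits of the samples, were chosen before theirs. The interferon genes under other splits, the interferon level of ABPC_EV against FBMSC_EV, and the spread with the erythroid list taken out, were read after. Groups of 3 were not tested for outlying libraries.

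For 5 gene lists the medians against PBS lay on opposite sides of the all-gene median under the 2 EV preparations, and the direct comparison, which tests the difference itself, passed. In none of the 5 did both changes against PBS pass, and by the sign of the test, platelet and antioxidant genes were lower under both preparations. For neutrophil genes ABPC_EV minus FBMSC_EV was -0.62 (against PBS -0.25 and 0.38; camera adjusted p = 8.54e-15, and 0.549 with an estimated correlation). For platelet genes it was 0.51 (0.07 and -0.52; adjusted p = 1.19e-05, and 0.817), and for plasma cell genes 0.50 (0.27 and -0.19; adjusted p = 0.0403, and 0.857). For antioxidant genes it was -0.40 (-0.19 and 0.06; adjusted p = 2.47e-05, and 0.791), and for autophagy genes -0.12 (-0.02 and 0.14; adjusted p = 0.0237, and 0.857). None of these differences passed with an estimated correlation. Single libraries moved them: the neutrophil one was -0.18 without FBMSC_EV replicate 1 and -0.39, -1.001 and -0.30 without ABPC_EV replicates 1, 2 and 3, and its change under ABPC_EV was -0.01 and -0.53 without PBS replicates 2 and 3 and -0.02, -0.62 and 0.01 without ABPC_EV replicates 1, 2 and 3. The antioxidant one was -0.16 without FBMSC_EV replicate 1, and -0.61 and -0.21 without ABPC_EV replicates 2 and 3, and its change under ABPC_EV was -0.03, -0.32 and -0.05 without PBS replicate 2 and ABPC_EV replicates 2 and 3. The platelet one was 0.33 without FBMSC_EV replicate 3, and 0.09 and 0.89 without ABPC_EV replicates 2 and 3. The plasma cell one was 0.33 and 0.32 without ABPC_EV replicates 1 and 2. The autophagy one was -0.04, -0.20 and -0.18 without FBMSC_EV replicates 1, 2 and 3, and -0.06, -0.25 and -0.06 without ABPC_EV replicates 1, 2 and 3. Platelet genes missed the threshold without ABPC_EV replicate 2 (adjusted p = 0.071), and plasma cell and autophagy genes without FBMSC_EV replicate 1 (0.152 and 0.213). After median-ratio scaling 3 of the lists lay below the median under both preparations: platelet (-0.06 under ABPC_EV and -0.48 under FBMSC_EV), plasma cell (-0.04 and -0.25) and antioxidant (-0.66 and -0.19). For these lists no technical or biological explanation was tested.

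Nearly all genes were listed higher under ABPC_EV than under PBS. A lower erythroid share of a fixed total raises every other gene. With that list taken out the per-library median level still differed by 0.731 (SE 0.242, n = 3 each), which argues against it as the whole cause. The median fold change went from 1.41 to 0.75 and its median SE from 0.36 to 0.39. By limma 0 genes then passed (4497 at an unadjusted p under 0.05), so the calls ended with a smaller fold and a slightly wider spread. These 2 medians are not on a like scale, because 1 was added after the remainder had been rescaled upward. Their difference therefore does not measure the part that the erythroid share accounts for. Deeper sequencing as a whole is argued against by the ratio of recovered reads, 0.958; outside the erythroid list that ratio was 1.75 (exact permutation p = 0.1), so low values rest on more reads under ABPC_EV, and an effect of that stays open. Part of the shift may still come from the erythroid share, and other abundant transcripts, a batch that follows the groups and a response to the injection stay open. Blood cell counts, which would separate fewer reticulocytes from more leukocyte RNA, are not among the deposited values.

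Interferon-stimulated genes were high under FBMSC_EV. That 1 library carries the list is argued against by its relative median, which stayed between 0.60 and 0.95 when each of the 6 compared libraries was left out. The list passed in 9 of 9 fits, counting 3 that left out an ABPC_EV library, but that call tells the groups apart poorly: with an estimated correlation it had an adjusted p of 0.118, and it also passed in 5 of the 9 other splits, with a relative median of up to 0.77 against 0.79. More monocyte RNA may account for part of it. The interferon level minus the monocyte level differed from PBS by 0.145 (SE 0.373, n = 3 each), against 0.588 (SE 0.369) for the interferon level alone. For ABPC_EV minus FBMSC_EV these were -0.388 (SE 0.315) and -0.774 (SE 0.163). FBMSC_EV replicate 3 went the other way. Its interferon minus monocyte level was 0.214, against -0.624 and -0.684 in FBMSC_EV replicates 1 and 2. The monocyte level of that library was 3.43, like the PBS mean of 3.43. With SEs of this size, and with PBS replicate 1 at 3.61 among FBMSC_EV libraries at 3.24 to 3.64, an infection or other exposure of single animals and a response to FBMSC_EV also stay open.

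HBG2 was low in both EV groups. HBG2 minus the erythroid list differed from PBS by -4.524 under ABPC_EV (SE 1.47, n = 3 each) and by -4.00 under FBMSC_EV (SE 1.32). HBG2 minus HBB differed by -3.776 (SE 1.32) and -3.35 (SE 1.19). HBG2 thus fell further than that list and than HBB. It was named for its fall in the same libraries, so these differences largely restate its change. They cannot exclude a general fall of erythroid RNA, or reads shared with HBB in a fixed proportion, as part of it. The PBS libraries differed widely among themselves, with an SD of 624 around a mean of 553, and without PBS replicate 1 the call under FBMSC_EV ended (adjusted p = 0.129). Differences between animals in fetal globin, reads shared with other gamma-globin copies and an effect of the injections may each underlie it and stay open.

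The splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. For ABPC_EV against PBS the real split gave 9639 genes and the highest other 5 (1 of the 10 splits gave as many), and for lists 9 against 14 (9 of 10). On scaled recovered reads it gave 242 genes, but PBS replicate 3 with ABPC_EV replicates 1 and 3 gave 1027 (2 of 10), so a structure of the samples other than the groups may contribute to the 242; no such structure was tested. For FBMSC_EV against PBS the real split gave 28 genes and the highest other 30 (2 of 10), and for lists 11 against 12 (4 of 10). For ABPC_EV against FBMSC_EV it gave 68 genes against 60 (1 of 10), and 16 lists against 13 (1 of 10).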

How the results depend on the processing

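Median-ratio scaling, limma-voom on recovered reads with that scaling, quantile normalization for lists, the pseudocount of 0.5, disjoint controls and the estimated correlation with a library left out were chosen after the data were seen. For the values below that moved or reversed, the cause was not tested, except where a setting's construction is named. Counts are given in the order ABPC_EV against PBS, FBMSC_EV against PBS, ABPC_EV against FBMSC_EV; as designed they were 9639, 28 and 68 genes and 9, 11 and 16 lists.

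With limma, 0, 0 and 0 genes passed with the erythroid list taken out (4497, 1170 and 536 at an unadjusted p under 0.05), after quantile normalization (1054, 474 and 559) and after median-ratio scaling (1080, 512 and 568). On recovered reads limma-voom gave 8715, 6244 and 60 genes unscaled, and 242, 0 and 0 scaled (2507, 879 and 1250 at an unadjusted p under 0.05); 64 of the 242 were among the 9639, 19 in the same direction and 45 in the opposite one. The filter at 10 gave 2653, 575 and 35 genes from fewer genes tested, and no filter 11691, 1 and 11. The replicate block gave 9682, 44 and 3406, although replicate numbers do not pair the animals, and the 6 samples alone 9616, 1063 and 23. An adjusted p under 0.1 gave 9903, 3523 and 4865, an unadjusted p under 0.05 with a 2-fold change 8506, 1836 and 1549, and pseudocounts of 0.1, 0.5 and 5 gave 9594, 184 and 9, then 9650, 36 and 46, then 9554, 0 and 2980.

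Lists past the threshold were 2, 0 and 2 with an estimated correlation (with each library left out these 4 held in 2, 1, 0 and 0 of 9 fits, in the order erythroid and mitochondrial, then erythroid and interferon-stimulated) and 26, 1 and 0 by fry, which tests each list without comparing it to other genes. All of fry's calls were higher, and those for ABPC_EV against PBS include the ribosomal, mitochondrial, antioxidant and oxidative phosphorylation lists (adjusted p = 0.0134, 0.0432, 0.00489 and 0.0056), which were lower relative to other genes. They were 6, 9 and 13 with the erythroid list taken out or after quantile normalization, 8, 9 and 10 with the filter at 10, 8, 11 and 15 with the block, 9, 11 and 13 after median-ratio scaling, and 12, 10 and 10 on scaled recovered reads. The correlation of fold changes, 0.623 as designed, was 0.575 with the erythroid list taken out, 0.588 with the filter at 10, 0.623 after scaling and 0.674 on scaled recovered reads; with disjoint controls it ranged from 0.054 to 0.476, and from -0.148 to 0.346 after scaling.

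With each library left out, genes ranged from 8728 to 9699, from 13 (without PBS replicate 1) to 4526 (without PBS replicate 3) and from 45 (without ABPC_EV replicate 3) to 4863 (without ABPC_EV replicate 1) as designed. After scaling they ranged from 0 to 130, 0 to 2 and 0 to 1, and on scaled recovered reads from 0 to 516, 0 to 0 and 0 to 1. Lists ranged from 6 to 12, 7 to 14 and 8 to 16 over these fits, and the correlation from 0.449 to 0.766. For ABPC_EV against PBS, ALAS2 ranged from -0.31 without PBS replicate 3 to 0.31 without PBS replicate 2, and ATP6 from -0.92 without PBS replicate 1 to 0 without PBS replicate 3.

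The named genes have 151 values, counting a gene once per comparison in which it is named; of their 3063 values under alternatives, 2314 kept their direction and side of the threshold, 483 kept the direction but lost the threshold, 185 gained it and 81 reversed. Under quantile normalization these reversed for ABPC_EV against PBS: AZU1 -0.26, BPI -0.16, EPB41 -0.48, GLRX -0.21, GYPC -0.67, LTF -0.12, NAMPT -0.26, ND3 -0.48, ND4 -0.32 and RHAG -0.19, with HBB at 0 because it ranks first in every library. For FBMSC_EV against PBS they were AZU1 -0.0018, FAU -0.11, FKBP11 -0.13, POLB -0.086, PRDX1 -0.22 and PRKAR2B -0.088. For ABPC_EV against FBMSC_EV they were CLEC10A -0.040, CYCS -0.064, FASLG -0.13, NR4A1 -0.020, PSMD6 -0.065, RETN -0.093, TCF7L2 -0.098 and TNF -0.0049.

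After median-ratio scaling, which takes the median shift away by construction, the reversed values for ABPC_EV against PBS were AZU1 -0.21, BPI -0.091, EPB41 -0.75, GLRX -0.52, GYPC -0.82, HBA1 -1.73, LTF -0.27, NAMPT -0.48, ND1 -0.34, ND3 -0.53, ND4 -0.71 and RHAG -0.073. For FBMSC_EV against PBS they were FAU -0.42, FKBP11 -0.13, POLB -0.096, PRDX1 -0.24 and PRKAR2B -0.041. For ABPC_EV against FBMSC_EV they were CLEC10A -0.038, CYCS -0.084, FASLG -0.17, NR4A1 -0.0014, PSMD6 -0.19, RETN -0.14, RPL22 -0.23 and TCF7L2 -0.075.

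On unscaled recovered reads HBA1 (-0.40) and ND3 (-0.41) reversed for ABPC_EV against PBS. On scaled recovered reads the same comparison reversed AZU1 -0.45, BPI -0.65, EPB41 -0.95, GLRX -0.68, GYPC -1.17, HBA1 -2.24, HK1 -0.11, LTF -0.36, NAMPT -0.82, ND2 -0.40, ND3 -1.27, ND4 -0.61, PSMB2 -0.097 and RHAG -0.73. FBMSC_EV against PBS reversed AZU1 -0.015, CLEC10A -0.25, FAU -0.58, FKBP11 -0.31, POLB -0.019, PRDX1 -0.23 and PRKAR2B -0.29. ABPC_EV against FBMSC_EV reversed CYCS -0.084, NR4A1 -0.43, PSMD6 -0.14, RPL22 -0.26, TCF7L2 -0.46 and TNF -0.25.

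DESeq2, its size factors and total library sizes were named beforehand for counts only. They were tried once on the recovered reads, after the other results were known, and set aside because those reads are rebuilt from a TPM-like unit and are not counts. In that trial DESeq2 called genes in each of the 3 comparisons, edgeR with TMM or with the size factors called 0 in each, and edgeR with total library sizes called genes in each, most of them for ABPC_EV against PBS. The 0 counts after scaling therefore depend on the tool. The trial's values are not in the tables; limma-voom on the same reads, also named for counts, was kept as an exception. Depth limits the low values: outside the erythroid list the libraries hold 3.02 M to 8.09 M recovered reads, fewest in PBS replicate 1, so a gene with a value of 1 rests on few reads.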
